A study of Burkholderia stagnalis with 18 samples.

How the data were processed

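The libraries hold total RNA of *Burkholderia stagnalis* TBRC 18363 from LS2 cultures at 25 or 30 °C harvested at 24, 30 or 48 h, extracted with a RiboPure kit and treated with DNase I, and sequenced as paired-end 150 base Illumina reads. The deposited table gives, per the labels of its 18 columns, raw counts for 7621 protein-coding features with RAST product names, and the submitters' processing notes name FastQC, MultiQC and HISAT2. The counting tool, strand setting and genome build are not given in the sources used here, so overlapping or antisense reads could not be assigned, and counts of near-identical copies (a pair each of EF-Tu, GroEL and RpoD genes) are uncertain. The table holds no symbols, lengths or coordinates, 2179 features are named hypothetical protein, 18 had 0 counts in every library, and 0 pairs of libraries were identical. Replicate numbers come from the labels, which do not say whether replicates were separate cultures, so p-values measure the spread between these libraries alone.

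Samples were put in 6 groups of 3 by temperature and time, and groups, tests, gene lists, the rule for named genes and the alternatives not marked as later were fixed before the data were examined. Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 7298, and scaled by TMM (factors 0.89 to 1.18). One edgeR quasi-likelihood model (glmQLFit, robust) with a mean per group and 12 residual degrees of freedom gave 7 pairwise contrasts, the temperature effect averaged over times, the interaction of temperature with 48 h against 24 h, and the test of any difference. All tests were two-sided, and p-values were adjusted by Benjamini-Hochberg with a limit of 0.05. The common biological coefficient of variation was 16.76%, and correlations of log2 CPM (prior count 2) within a group were at least 0.967. On data simulated for the comparison at 24 h the model called 25.76% of genes changed 1.5-fold, 61.54% changed 2-fold and 95.45% changed 4-fold. Of calls 4.00% were false. With more genes called in the real data these shares may differ.

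Gene lists, 38 with at least 3 measured members, were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. All 102 list calls of 342 tests are lost with an estimated correlation, where 33 of all 342 tests reach an unadjusted p under 0.05. The patterns that define the lists were fixed before the data were examined but for other product names, and their wording was adapted to RAST names after the names, not the values, were seen: ribosomal proteins went from 4 to 56 features, NADH dehydrogenase from 0 to 15 and quorum sensing from 25 to 4. The list of ribosomal RNA and tRNA genes had 0 members.

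Strong genes were the top 5% by mean log2 CPM over groups, and steady ones had group means within 2-fold, tested for equivalence with limma over all 15 pairs of groups. Named genes were the 10 largest rises and falls (5 for the steps to 30 h, temperature at 30 h, the averaged contrast and the interaction) past the test, with a product name, at least 20 CPM in the higher group and, but for the interaction, all 3 libraries of one group above all 3 of the other. Also named were the largest rise and fall and up to 2 more members of each list, the 20 strongest equivalent genes, reference genes, and the 10 genes with the highest CPM. Alternatives were DESeq2 size factors, library totals, no filter on low counts, DESeq2's Wald test, limma-voom, a 2-fold minimum (glmTreat), fits of the compared groups alone, a replicate block, other limits for strong and steady genes, and leaving out each library. Replicate numbers were not used as pairs in the main model: 9 of 45 same-numbered pairs of libraries had correlated deviations over 0.1 (range -0.08 to 0.22, median 0.05 against -0.02 for other pairs), though 11 of 18 libraries correlated best with one of their own number. With the replicate block 3 more lists passed.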

Results

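Messenger RNA of *Burkholderia stagnalis* TBRC 18363, a soil bacterium of a genus known for its secondary metabolites, was counted by RNA sequencing of cultures grown in LS2 medium at 25 or 30 °C and harvested at 24, 30 or 48 h. The 6 groups, here called 25C_24h, 25C_30h, 25C_48h, 30C_24h, 30C_30h and 30C_48h, held 3 libraries each. Total counts ran from 8352949 to 13891324 per library over 7621 protein-coding features, of which 7298 were tested. The series title sets strong constitutive promoters as the aim. Levels are CPM, counts scaled to library size, given as mean ± SD with n = 3 libraries per group, changes are log2 fold changes unless written as a fold, and features carry the peg numbers of the count table.

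Between-group variation exceeded replicate variation in most genes, with 5875 of 7298 genes (80.50%) past the test for any difference among the 6 groups. The first component of log2 CPM held 42.34% of the variance and the second 21.47%. On the first component the 6 libraries of 24 h lay between -42.88 and -29.71, those of 30C_48h between 22.79 and 24.29, and those of 25C_48h between 49.18 and 76.11. On the second, 25 °C lay between -34.71 and -5.72 and 30 °C between 14.36 and 36.58. Replicates within 30C_24h and 25C_48h differed more than others, since replicate 2 of 30C_24h reached a chi-square per degree of freedom of 86.11 against replicate 3, and replicates 1 and 2 of 25C_48h reached 70.67, where the lowest of the 18 replicate pairs was 12.56. Against replicate 3 of 25C_48h, replicate 2 reached 29.01 and replicate 1 18.07. Without replicate 2 of 30C_24h 5733 genes passed when replicate 1 of 25C_48h was left out too and 6105 when its replicate 2 was, choices made after those values were seen.

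**Figure D1:**
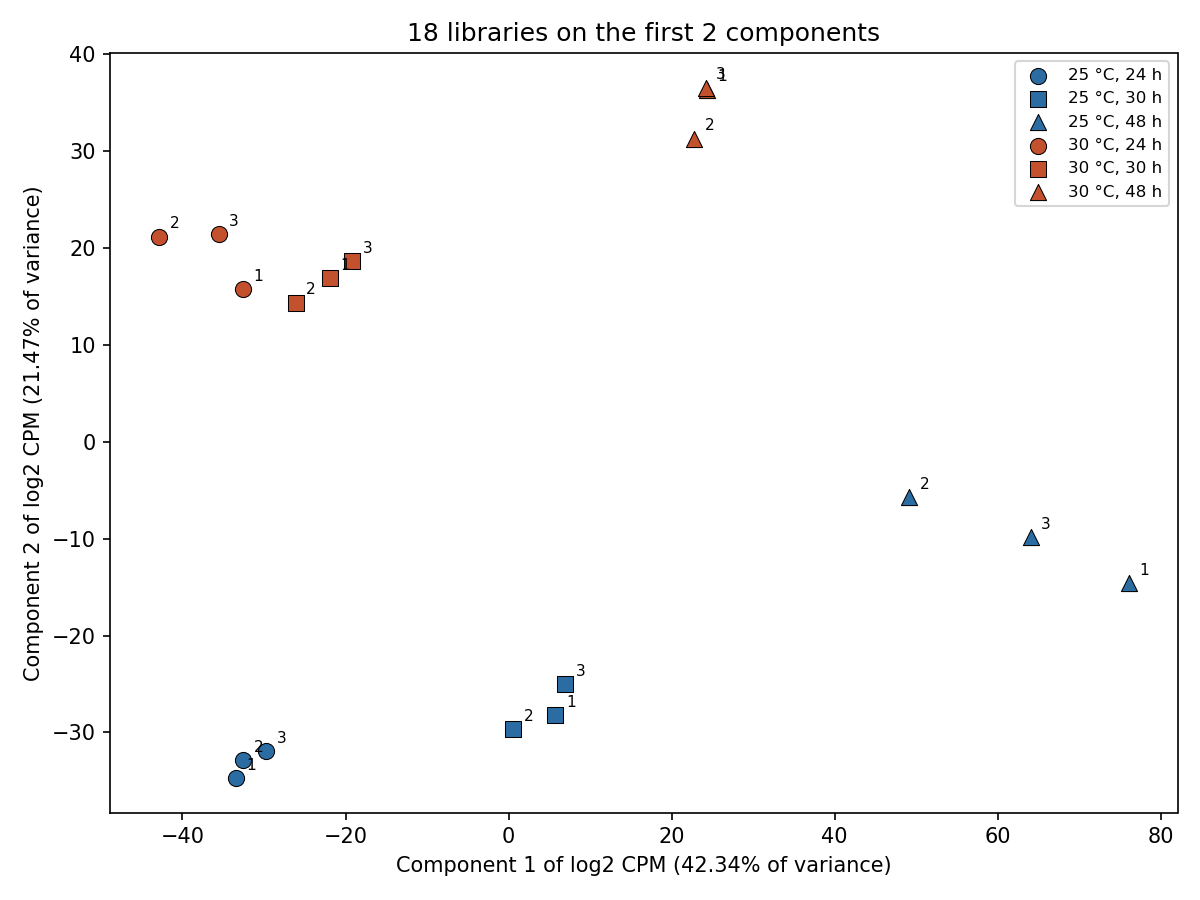
Each point is 1 of 18 libraries on the first (42.34% of variance) and second (21.47%) components of log2 CPM, coloured by temperature, shaped by harvest time and numbered by replicate. Libraries of 24 h lie between -42.88 and -29.71 on the first component.

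Which genes are expressed strongly and steadily over temperature and time was asked of the 364 genes in the top 5% by mean log2 CPM (at least 510 CPM). A hypothetical protein, peg.4867, had the highest level, 24400 CPM, which was 1.67% to 2.91% of the counts of a library, and its group means spanned 0.74. An autotransporter (peg.4189, 11000 CPM, range 0.96), a polyketide synthase (peg.7117, 10500 CPM, range 1.16), the hypothetical proteins peg.5120 (8860 CPM, range 0.29) and peg.5330 (7960 CPM, range 0.71), and a further polyketide synthase (peg.2074, 7700 CPM, range 1.21) followed. The other 4 of the top 10 were the hypothetical protein peg.4682 (6330 CPM, range 9.04, 525-fold), a granule-associated protein (peg.2571, 6020 CPM, range 1.41), a porin (peg.5662, 5990 CPM, range 1.55) and a polyhydroxybutyrate depolymerase (peg.7217, 5720 CPM, range 1.47). Of the 364 strong genes, 158 (43.41%) had group means within 2-fold of each other, against 3126 (42.83%) of all 7298 genes, and the median range was 1.10 for strong genes and 1.11 for all. An equivalence test within that 2-fold limit was passed by 65 strong genes, 5 of them hypothetical, with ranges from 0.26 to 0.69, and 48 of the 65 also passed the test for any difference.

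Among the 20 equivalent genes with the highest level, the hypothetical protein peg.5120 was first (adjusted p = 0.00395 for equivalence). Ribosomal protein S1 (peg.1182) had 2990 CPM and a range of 0.51, the ClpA protease subunit (peg.3013) 2650 CPM and 0.60, the polyhydroxyalkanoate synthetase (peg.5012) 2390 CPM and 0.46, and the RNA polymerase subunit RpoC (peg.451) 2140 CPM and 0.40. Further down stood an AraC-type regulator (peg.5953, 1750 CPM, range 0.54), malate dehydrogenase (peg.5727, 1500 CPM, range 0.49), methylmalonyl-CoA mutase (peg.7469, 1500 CPM, range 0.56), the Flp pilin (peg.5617, 1480 CPM, range 0.60), the pilus ATPase TadA (peg.5611, 1210 CPM, range 0.43) and acetoacetyl-CoA reductase (peg.2209, 1190 CPM, range 0.63). The 7 further ones (peg.7453, peg.3023, peg.7451, peg.4474, peg.7187, peg.7112 and peg.7467) had 1100 to 1710 CPM.

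Of 22 genes often used as references, 11 were strong, 14 had a range within 2-fold and, of the 11 strong ones, which alone were tested for equivalence, 4 passed. Those 4 were the RNA polymerase subunit RpoB (peg.450, 1620 CPM, range 0.56, adjusted p = 0.0129), the DNA polymerase subunit DnaE (peg.2824, 600 CPM, range 0.39, adjusted p = 0.0027), the recombinase RecA (peg.3155, 597 CPM, range 0.61, adjusted p = 0.00611) and the sigma factor RpoD (peg.5834, 1390 CPM, range 0.62, adjusted p = 0.0199). The cell division protein FtsZ (peg.671, 2260 CPM, range 0.68, adjusted p = 0.0525), an elongation factor Tu gene (peg.443, range 0.65, adjusted p = 0.0816) and the gyrase subunit GyrA (peg.1175, range 0.83, adjusted p = 0.321) stayed within 2-fold and did not pass. Ranges over 2-fold were measured for the ATP synthase beta chain (peg.236, 1.43), glutamate synthase (peg.514, 1.36), both pyrroline-5-carboxylate reductases (peg.6566, 1.32, and peg.840, 1.22), another RpoD gene (peg.6926, 1.28, or 0.87 without replicate 2 of 30C_24h), GroES (peg.971, 1.12), ribosomal protein S7 (peg.454, 1.11) and GroEL (peg.972, 1.01). By list, equivalent genes numbered 5 of 7 strong RNA polymerase and sigma factor genes (23 measured), 5 of 7 type VI secretion genes (84) and 4 of 5 polyhydroxyalkanoate genes (9). The counts were 4 of 9 strong fimbrial genes (66 measured), 3 of 11 ribosomal protein genes (56) and 2 of 10 nonribosomal peptide and polyketide genes (22). By the limma equivalence test 17 lists with strong members had 0 equivalent genes, most of all the porin (12 strong of 90, 1 at an unadjusted p under 0.05), stringent response (8 of 19, 0) and phosphate starvation (7 of 32, 0) lists. Feature lengths were not used, so the order by CPM favours long genes such as polyketide synthases.

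**Figure D2:**
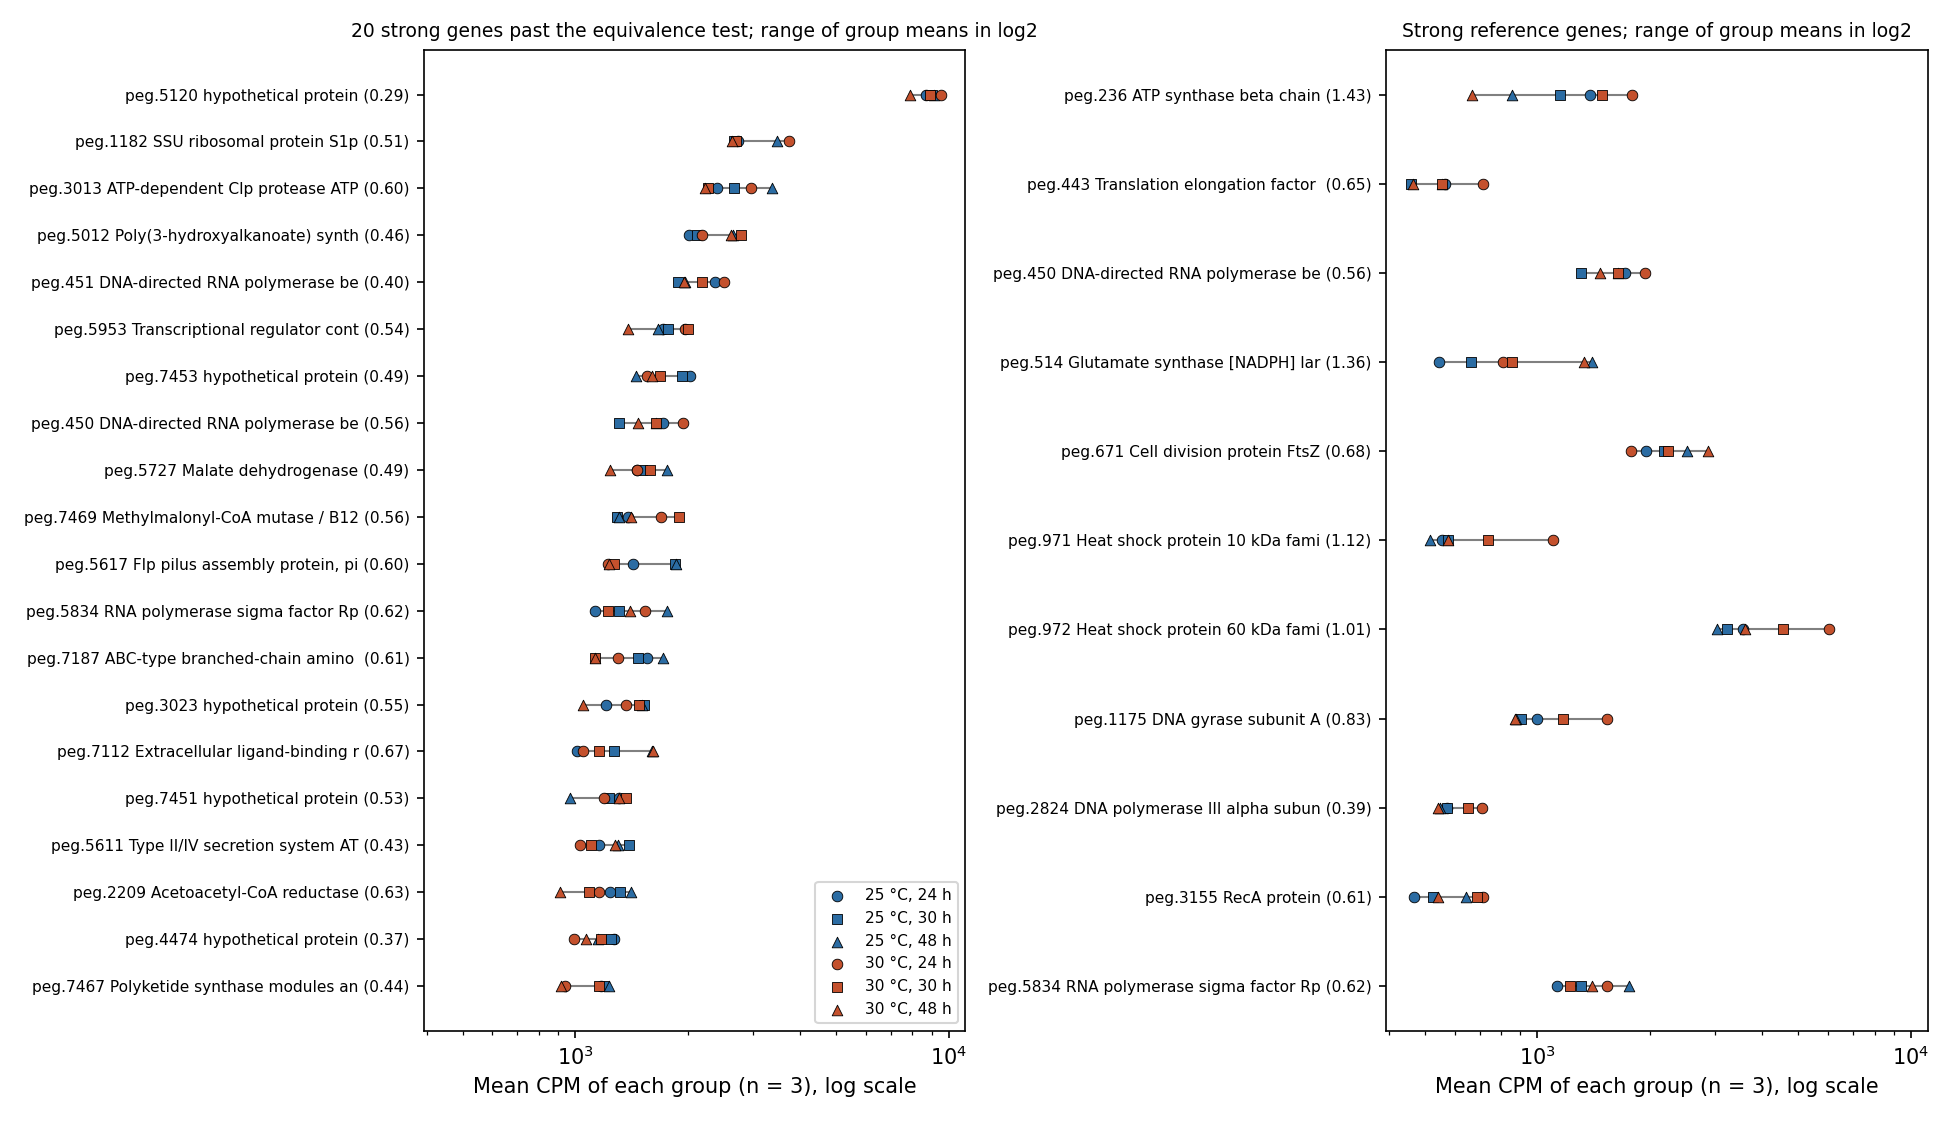
Symbols give the mean CPM of each group (n = 3, log axis) for the 20 equivalent genes with the highest level (left) and the 11 strong reference genes (right), with the range of group means in log2 in brackets. Ranges on the left run from 0.29 for peg.5120 to 0.67 for peg.7112, and on the right from 0.39 for peg.2824 to 1.43 for peg.236.

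At 24 h, growth at 30 °C was compared with 25 °C. The largest falls were in genes named for inositol breakdown and in features close to them in number. Myo-inositol 2-dehydrogenase (peg.1692) fell 115-fold, from 331 ± 56.5 to 2.88 ± 0.367 CPM (-6.84, SE 0.31, adjusted p = 1.29e-12), and the substrate-binding protein of a sugar transporter (peg.1688) fell from 213 ± 36.8 to 3.26 ± 0.438 CPM (-6.02). The other 8 of the 10 largest falls (peg.1683, peg.1684, peg.1685, peg.1689, peg.1690, peg.1691, peg.1693 and peg.1694) were -5.61 to -6.61. Hydroxylamine reductase (peg.3938) rose 13.1-fold, from 230 ± 13.4 to 3020 ± 272 CPM (3.72), and its NADH oxidoreductase (peg.3939) rose 17.5-fold, from 89.8 ± 4.75 to 1570 ± 108 CPM (4.13, adjusted p = 1.05e-09). A cytochrome c family protein (peg.3936) rose by 3.99 and octanoyltransferase (peg.3454) by 2.78, from 175 ± 24.3 to 1200 ± 245 CPM. The genes peg.3941 and peg.4577 rose by 3.77 and 2.67. Replicate 2 of 30C_24h carried much of 4 other large rises: without it the repressor BetI (peg.4031) went from 4.98 to 3.84, ornithine cyclodeaminase (peg.6208) from 4.02 to 2.08, betaine aldehyde dehydrogenase (peg.4030) from 2.73 to 2.07, and CidA (peg.172) from 3.92 to 0.68, no longer past the test (adjusted p = 0.0712).

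Temperature at 24 h raised 1450 genes and lowered 1523, of which 460 and 511 changed at least 2-fold, and 52.82% of genes separated the 6 libraries fully where chance gives 10%. Of 56 ribosomal protein genes, 45 rose and 0 fell (48 and 1 adjusted over the list alone, median 0.65, adjusted p = 7.97e-11, or adjusted p = 0.46 with an estimated correlation). Of 15 translation factor genes, 7 rose and 1 fell (11 and 1 adjusted over the list alone, median 0.41, adjusted p = 0.00392, or adjusted p = 0.419 with an estimated correlation). Elongation factor P (peg.1284) rose from 140 ± 9.5 to 360 ± 81.4 CPM. The elongation factor G gene peg.3025 fell by 0.31, a call that ended without replicate 1 (adjusted p = 0.139) or 2 (0.094) of 25C_24h or replicate 2 of 30C_24h (0.0891). Of 11 ATP synthase genes, 8 rose and 0 fell (11 and 0 adjusted over the list alone, median 0.67, adjusted p = 4.19e-04, or adjusted p = 0.326 with an estimated correlation). Of 15 NADH dehydrogenase genes, 9 rose and 0 fell (9 and 0 adjusted over the list alone, median 0.40, adjusted p = 4.19e-04, or adjusted p = 0.419 with an estimated correlation). Of 27 terminal oxidase genes, 12 rose and 3 fell (14 and 4 adjusted over the list alone, median 0.34, adjusted p = 0.0201, or adjusted p = 0.419 with an estimated correlation). Cytochrome o oxidase subunit III (peg.3241), part of an oxygen-reducing quinol oxidase, rose from 282 ± 9.32 to 1050 ± 149 CPM. Of 31 chaperone and heat shock genes, 17 rose and 4 fell (18 and 5 adjusted over the list alone, median 0.51, adjusted p = 0.00493, or adjusted p = 0.419 with an estimated correlation). ClpB (peg.2264), a protein disaggregase, rose from 838 ± 46.7 to 2050 ± 566 CPM and the protease subunit HslV (peg.33) from 91.2 ± 15.3 to 242 ± 72.7 CPM.

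Of 29 DNA repair genes, 12 rose and 1 fell (12 and 1 adjusted over the list alone, median 0.29, adjusted p = 0.0201, or adjusted p = 0.326 with an estimated correlation). The helicase UvrD (peg.1706) rose from 206 ± 5.93 to 522 ± 62.6 CPM. Of 32 cell division and wall genes, 18 rose and 1 fell (19 and 1 adjusted over the list alone, median 0.40, adjusted p = 4.19e-04, or adjusted p = 0.326 with an estimated correlation). FtsI (peg.5354), a peptidoglycan transpeptidase, rose from 219 ± 5.11 to 529 ± 95.8 CPM. Of 22 reference genes, 12 rose and 1 fell (14 and 1 adjusted over the list alone, median 0.44, adjusted p = 0.00155, or adjusted p = 0.423 with an estimated correlation). Of 32 phosphate starvation genes, 1 rose and 22 fell (1 and 23 adjusted over the list alone, median -0.53, adjusted p = 5.6e-05, or adjusted p = 0.419 with an estimated correlation). An aminoethylphosphonate transporter gene (peg.3823) fell from 460 ± 80.6 to 132 ± 46.1 CPM. Of 10 secreted enzyme genes, 0 rose and 4 fell (0 and 5 adjusted over the list alone, median -0.38, adjusted p = 0.0262, or adjusted p = 0.419 with an estimated correlation). Chitinase (peg.1998) fell from 3210 ± 89.3 to 1080 ± 144 CPM and an extracellular protease (peg.4735) from 334 ± 23.6 to 120 ± 12.3 CPM. Without replicate 2 of 25C_24h the secreted enzyme list did not pass (adjusted p = 0.0538). Of 57 aromatic catabolism genes, 2 rose and 23 fell (2 and 23 adjusted over the list alone, median -0.33, adjusted p = 0.0201, or adjusted p = 0.419 with an estimated correlation). Fumarylacetoacetase (peg.927), the last enzyme of tyrosine breakdown, fell from 601 ± 68 to 103 ± 4.74 CPM. Of 49 amino acid transport genes, 5 rose and 20 fell (6 and 23 adjusted over the list alone, median -0.39, adjusted p = 0.00392, or adjusted p = 0.326 with an estimated correlation). The oligopeptide transporter genes OppF (peg.3607) and OppB (peg.3604) fell by 4.76 and 4.01.

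**Figure D3:**
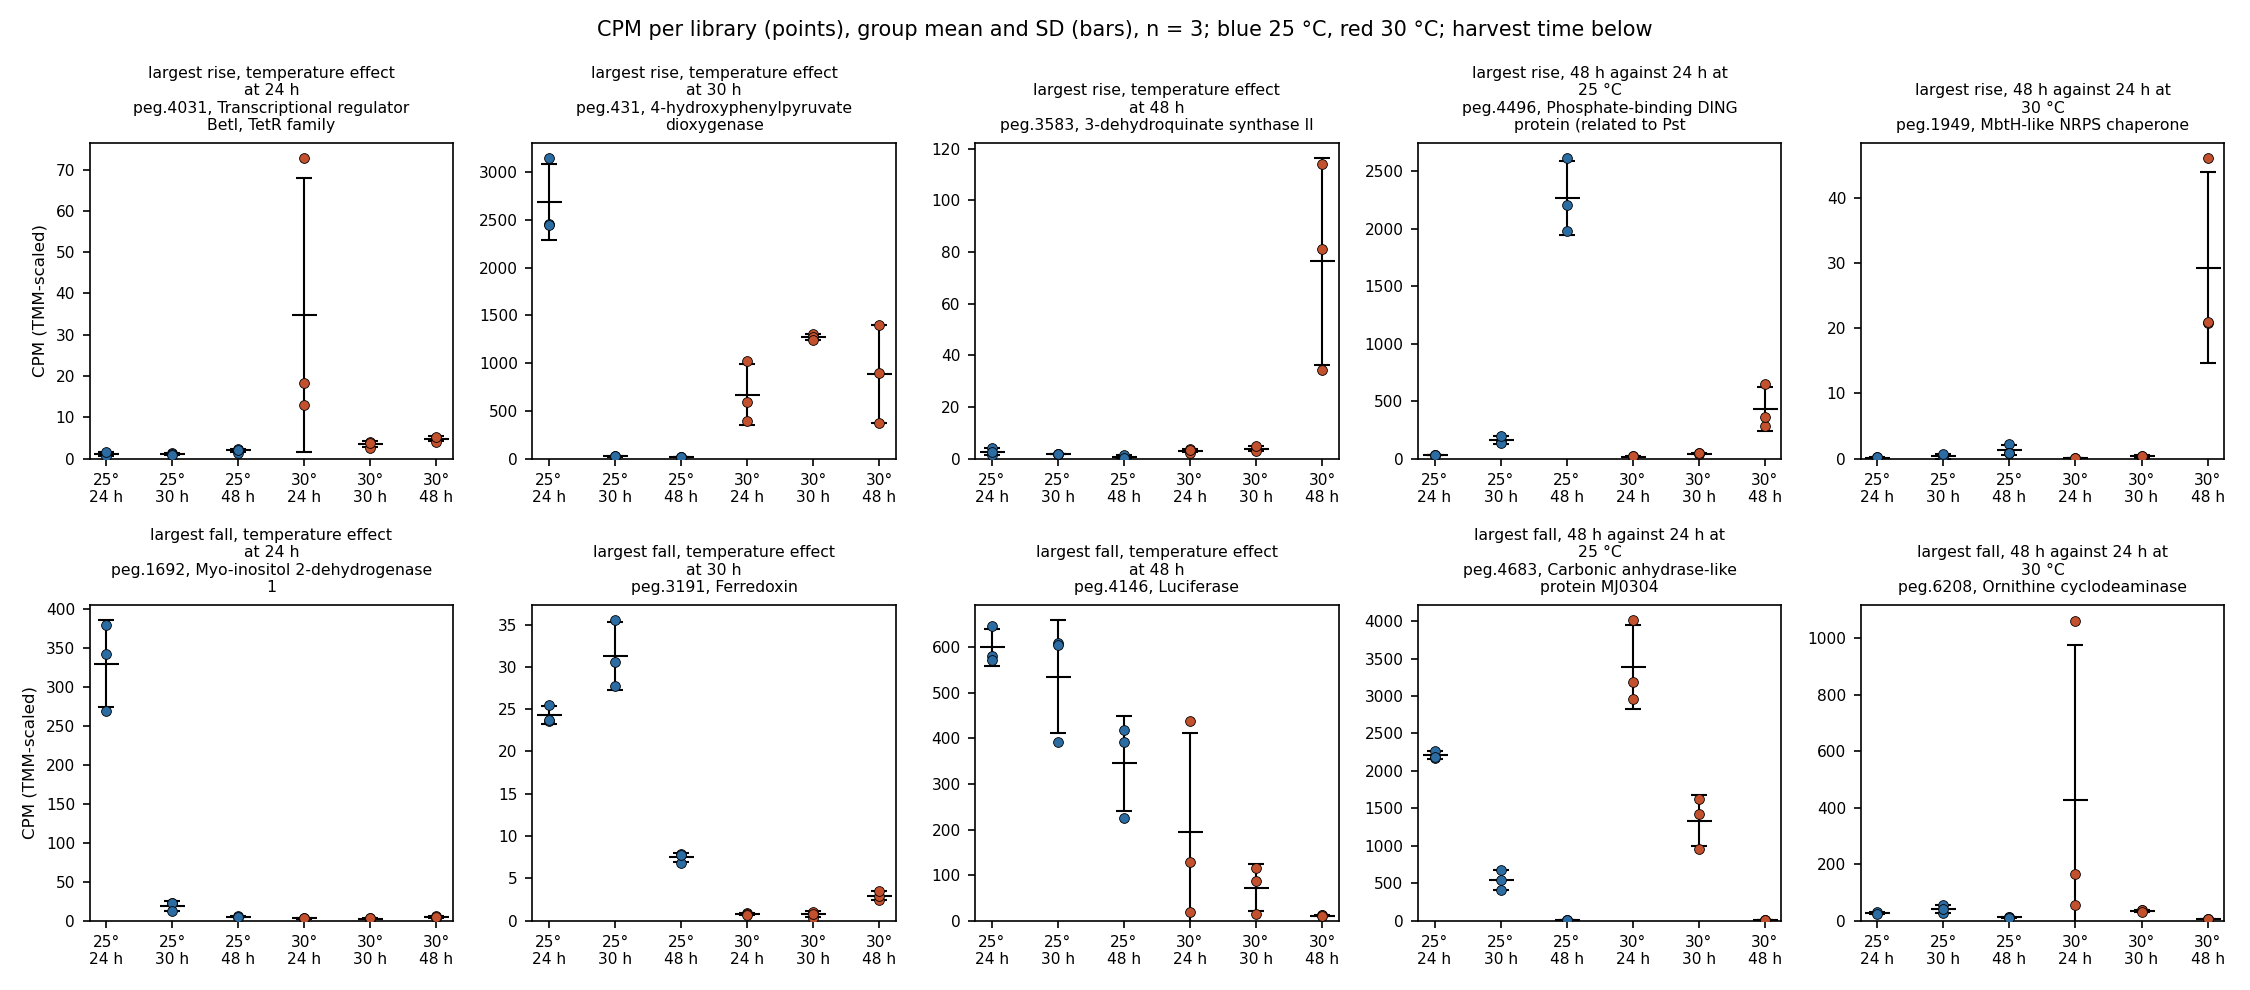
Points give CPM per library for the genes with the largest rise and the largest fall in 5 comparisons, each gene drawn once, with bars for the group mean and SD (n = 3). The gene peg.1692 stands at 331 ± 56.5 CPM in 25C_24h and 2.88 ± 0.367 CPM in 30C_24h. BetI (peg.4031) is highest in replicate 2 of 30C_24h.

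At 30 h the same comparison was made. The enzyme 4-hydroxyphenylpyruvate dioxygenase (peg.431), which acts in tyrosine breakdown, rose 58-fold, from 21.9 ± 1.55 to 1270 ± 29.3 CPM (5.86, SE 0.45, adjusted p = 1.06e-07). The phenylacetyl-CoA epoxidase subunit PaaE (peg.436) rose 25.2-fold, from 7.69 ± 0.767 to 193 ± 10.5 CPM, and PaaN2 (peg.651) from 34.9 ± 17 to 658 ± 54.8 CPM. Phenylacetate-CoA ligase (peg.4769) rose by 3.98, or 4.59 without replicate 2 of 25C_30h, and peg.437 by 3.92. Inosose isomerase (peg.3196) fell 26.8-fold, from 215 ± 5.67 to 8.01 ± 0.761 CPM (adjusted p = 1.25e-13), xylose isomerase (peg.7419) from 64.7 ± 6.77 to 2.2 ± 0.343 CPM, and phenylalanine-4-hydroxylase (peg.208) from 292 ± 206 to 11.5 ± 1.12 CPM. A ferredoxin (peg.3191) fell by 5.42 and its neighbour in numbering peg.3190 by 5.33, or by 6.14 without replicate 2 of 30C_30h.

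Temperature at 30 h raised 1063 genes and lowered 1301 (349 and 460 at least 2-fold), with 51.74% of genes fully separated (chance 10%). Among 57 aromatic catabolism genes, 21 rose and 10 fell (23 and 10 adjusted over the list alone, median 0.01, adjusted p = 0.0128, or adjusted p = 0.558 with an estimated correlation). The median lay between -0.05 and 0.05 on leaving out each library in turn, and the mean was 0.77. Among 56 ribosomal protein genes, 19 rose and 1 fell (19 and 1 adjusted over the list alone, median 0.31, adjusted p = 7e-04, or adjusted p = 0.877 with an estimated correlation). Among 11 ATP synthase genes, 9 rose and 0 fell (10 and 0 adjusted over the list alone, median 0.40, adjusted p = 0.00321, or adjusted p = 0.441 with an estimated correlation). Among 15 NADH dehydrogenase genes, 5 rose and 1 fell (9 and 1 adjusted over the list alone, median 0.31, adjusted p = 0.04, or adjusted p = 0.85 with an estimated correlation). This call ended without any 1 of 8 libraries: 25C_24h replicates 1 (adjusted p = 0.0538), 2 (0.0526) and 3 (0.0519), 25C_30h replicates 2 (0.0778) and 3 (0.13), 25C_48h replicate 3 (0.0552), 30C_24h replicate 3 (0.0551) and 30C_30h replicate 3 (0.135). Of 28 sulfur assimilation genes, 9 rose and 1 fell (9 and 1 adjusted over the list alone, median 0.40, adjusted p = 0.0207, or adjusted p = 0.57 with an estimated correlation). Of 22 nonribosomal peptide and polyketide genes, 8 rose and 0 fell (8 and 0 adjusted over the list alone, median 0.23, adjusted p = 0.0227, or adjusted p = 0.685 with an estimated correlation). The polyketide synthase peg.5004 rose from 177 ± 6.18 to 304 ± 13.1 CPM, and the list did not pass without replicate 3 of 25C_30h (adjusted p = 0.0511).

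Among 29 DNA repair genes, 12 rose and 0 fell (14 and 0 adjusted over the list alone, median 0.42, adjusted p = 0.00321, or adjusted p = 0.158 with an estimated correlation). Among 32 cell division and wall genes, 15 rose and 1 fell (17 and 1 adjusted over the list alone, median 0.37, adjusted p = 7e-04, or adjusted p = 0.441 with an estimated correlation). Among 22 reference genes, 7 rose and 0 fell (7 and 0 adjusted over the list alone, median 0.33, adjusted p = 0.00679, or adjusted p = 0.685 with an estimated correlation). Among 32 phosphate starvation genes, 2 rose and 19 fell (2 and 22 adjusted over the list alone, median -0.53, adjusted p = 7e-04, or adjusted p = 0.57 with an estimated correlation). Phospholipase C (peg.88), which frees phosphate from lipids, fell from 71.4 ± 10.3 to 24.3 ± 2.96 CPM and the phosphate-binding protein PstS (peg.7124) from 695 ± 53.1 to 351 ± 26.5 CPM. Among 10 secreted enzyme genes, 0 rose and 6 fell (0 and 7 adjusted over the list alone, median -0.81, adjusted p = 0.00332, or adjusted p = 0.441 with an estimated correlation). Among 49 amino acid transport genes, 5 rose and 11 fell (5 and 11 adjusted over the list alone, median -0.26, adjusted p = 0.0135, or adjusted p = 0.441 with an estimated correlation).

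By 48 h the temperature comparison showed higher siderophore and iron uptake genes at 30 °C, proteins that bring scarce iron into the cell. A nonribosomal peptide synthetase of siderophore type (peg.1957) rose 64-fold, from 2.19 ± 1.15 to 149 ± 74.3 CPM (6.00, adjusted p = 3.34e-10), its partner peg.1958 from 2.21 ± 0.852 to 85.5 ± 33.6 CPM, and the ferric hydroxamate binding protein peg.1954 by 5.30. Features close in number to each other rose too, with 3-dehydroquinate synthase II (peg.3583) at 6.63 (7.55 without replicate 2 of 25C_48h), a hydroxybenzoate hydroxylase (peg.3579) at 6.52, from 1.87 ± 1.31 to 177 ± 102 CPM, 3-amino-4-hydroxybenzoate synthase (peg.3584) at 5.08, and peg.3582 and peg.3580 at 5.85 and 5.76. The tyrosine enzyme peg.431 rose from 12.1 ± 1.11 to 891 ± 516 CPM and saccharopine dehydrogenase (peg.2111), an enzyme of lysine metabolism, from 25.3 ± 1.32 to 1080 ± 401 CPM. A luciferase-type protein (peg.4146) fell from 345 ± 105 to 10.7 ± 1.63 CPM, leucyl aminopeptidase (peg.4077) 15-fold, from 1200 ± 21.6 to 79.6 ± 29.9 CPM (adjusted p = 3.23e-11), and the protease bacillolysin (peg.4078) from 856 ± 96.2 to 79.1 ± 32.3 CPM. The surface polysaccharide deacetylase PgaB (peg.5516) fell from 330 ± 22.4 to 54.2 ± 11.4 CPM, and the TerD genes peg.6577 and peg.6576 fell by 2.83 and 2.67. The other 4 of the 10 largest falls (peg.3196, peg.6799, peg.6515 and peg.6326) were -2.51 to -2.82.

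Temperature at 48 h raised 1876 genes and lowered 1739 (886 and 493 at least 2-fold), with 55.04% of genes fully separated (chance 10%). Scaling by library totals moved the median of all genes by 0.20, and 69.03% of the genes past the test were then higher at 30 °C in place of 51.89%. Of 56 iron uptake and storage genes, 33 rose and 6 fell (34 and 6 adjusted over the list alone, median 0.84, adjusted p = 1.39e-05, or adjusted p = 0.3 with an estimated correlation). Bacterioferritin (peg.6649), which stores iron, fell from 175 ± 29.7 to 75.4 ± 16.2 CPM. Of 109 drug efflux genes, 40 rose and 12 fell (40 and 12 adjusted over the list alone, median 0.34, adjusted p = 0.0163, or adjusted p = 0.443 with an estimated correlation). The efflux protein peg.3572 rose by 4.90 (7.16 without replicate 2 of 25C_48h) and peg.3575 by 4.67. The 32 cell division and wall genes had 18 that rose and 3 that fell (18 and 5 adjusted over the list alone, median 0.44, adjusted p = 0.0144, or adjusted p = 0.398 with an estimated correlation). MurF (peg.662) rose from 95.7 ± 52.5 to 400 ± 32.4 CPM, and the list did not pass without replicate 2 of 25C_48h (adjusted p = 0.0575). The 57 aromatic catabolism genes had 20 that rose and 6 that fell (20 and 6 adjusted over the list alone, median 0.52, adjusted p = 0.00517, or adjusted p = 0.3 with an estimated correlation). Of 39 oxidative stress genes, 5 rose and 18 fell (5 and 18 adjusted over the list alone, median -0.42, adjusted p = 0.0163, or adjusted p = 0.3 with an estimated correlation). The 32 phosphate starvation genes had 6 that rose and 19 that fell (6 and 19 adjusted over the list alone, median -0.72, adjusted p = 0.0163, or adjusted p = 0.622 with an estimated correlation). Alkaline phosphatase (peg.1338) fell by 2.04 (2.87 without replicate 2 of 30C_48h). The 10 secreted enzyme genes had 1 that rose and 8 that fell (1 and 8 adjusted over the list alone, median -1.05, adjusted p = 0.0032, or adjusted p = 0.3 with an estimated correlation). Of 124 phage and mobile element genes, 7 rose and 37 fell (6 and 33 adjusted over the list alone, median -0.34, adjusted p = 0.0032, or adjusted p = 0.443 with an estimated correlation).

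Averaged over the 3 times, 30 °C raised 2059 genes and lowered 2037 (368 and 311 at least 2-fold). The cytochrome c family protein peg.3936 rose 9.82-fold (3.30, adjusted p = 1.67e-12), peg.4577 by 2.96, the NADH oxidoreductase peg.3939 by 2.92, the hydroxylase peg.3579 by 2.76, and cytochrome o oxidase subunit III (peg.3241) 6.36-fold (adjusted p = 7.16e-15). Inosose isomerase (peg.3196) fell 16.8-fold (-4.07, adjusted p = 2.69e-17), the ferredoxin peg.3191 by 3.92, a citrate symporter (peg.1995) by 3.26, the luciferase-type protein peg.4146 by 3.17 and xylose isomerase (peg.7419) by 3.07. By camera 10 lists passed, with higher medians for ribosomal proteins (0.33, adjusted p = 8.35e-05), ATP synthase (0.31), NADH dehydrogenase (0.28), iron uptake (0.39), DNA repair (0.30), cell division (0.34) and reference genes (0.24), and lower ones for phosphate starvation (-0.57, adjusted p = 8.35e-05), secreted enzymes (-0.57) and amino acid transport (-0.28). None of these 10 passed with an estimated correlation (adjusted p = 0.265 to adjusted p = 0.686). Without replicate 2 of 25C_48h the ATP synthase, NADH dehydrogenase and reference lists did not pass (adjusted p = 0.0633 for each), and the reference list also ended without replicate 2 of 30C_48h (0.0629). S20 (peg.3051) rose by 0.63 and FtsQ (peg.669) by 0.80, and OppA (peg.3603) fell by 2.06.

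From 24 to 30 h at 25 °C, the comparison asked which genes change as the culture ages. The tyrosine enzyme peg.431 fell 123-fold, from 2690 ± 404 to 21.9 ± 1.55 CPM (-6.94, adjusted p = 3.45e-08), fumarylacetoacetase (peg.927) from 601 ± 68 to 14.2 ± 2.05 CPM and homogentisate dioxygenase (peg.926) from 666 ± 78.1 to 16 ± 0.762 CPM. The gene peg.923 fell by 5.43 and phenylacetate-CoA ligase (peg.4769) by 5.47, or by 6.07 without replicate 2 of 25C_30h. Phenylalanine-4-hydroxylase (peg.208), which makes tyrosine, rose 23.3-fold, from 12.5 ± 1.43 to 292 ± 206 CPM (4.54), an ExbB family protein (peg.4514) from 9.29 ± 1.36 to 123 ± 11.1 CPM (adjusted p = 3.57e-11) and peg.4832 from 13 ± 1.17 to 166 ± 11.1 CPM. The gene for 5-oxoprolinase (peg.6243) rose by 3.80, or by 3.08 without replicate 3 of 25C_30h, and peg.6430 by 3.78.

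Between 24 and 30 h at 25 °C 646 genes rose and 459 fell (227 and 178 at least 2-fold, and 1936 in all when the 6 libraries were fitted alone), with 40.72% of genes fully separated (chance 10%). Of 32 phosphate starvation genes, 20 rose and 1 fell (22 and 1 adjusted over the list alone, median 0.75, adjusted p = 3.21e-09, or adjusted p = 0.295 with an estimated correlation). Phospholipase C (peg.88) rose from 16.9 ± 2.62 to 71.4 ± 10.3 CPM and PstS (peg.7124) from 267 ± 11.4 to 695 ± 53.1 CPM. Among 27 terminal oxidase genes, 9 rose and 3 fell (12 and 3 adjusted over the list alone, median 0.42, adjusted p = 0.0109, or adjusted p = 0.65 with an estimated correlation). CoxN (peg.399) rose from 85.1 ± 5.82 to 165 ± 12.2 CPM, and the list did not pass without replicate 1 of 25C_30h (adjusted p = 0.0654). The 56 ribosomal protein genes had 1 that rose and 3 that fell (0 and 0 adjusted over the list alone, median -0.20, adjusted p = 0.00158, or adjusted p = 0.829 with an estimated correlation). Of 25 TCA cycle and glyoxylate genes, 0 rose and 3 fell (0 and 1 adjusted over the list alone, median -0.14, adjusted p = 0.0462, or adjusted p = 0.713 with an estimated correlation). Its largest fall was that of methylisocitrate lyase (peg.3633), an enzyme of propionate breakdown, and the call ended without replicate 1 (adjusted p = 0.0912) or 3 (0.06) of 25C_24h, replicate 1 (0.0737) or 3 (0.0786) of 25C_30h, replicate 2 of 30C_24h (0.0542) or replicate 2 of 30C_30h (0.0522). Among 22 nonribosomal peptide and polyketide genes, 0 rose and 9 fell (0 and 9 adjusted over the list alone, median -0.45, adjusted p = 2.96e-07, or adjusted p = 0.295 with an estimated correlation). Of 57 aromatic catabolism genes, 0 rose and 17 fell (0 and 17 adjusted over the list alone, median -0.09, adjusted p = 3.01e-08, or adjusted p = 0.107 with an estimated correlation). The mean was -1.26, and PaaE (peg.436) fell from 292 ± 65.4 to 7.69 ± 0.767 CPM. Of 82 fatty acid genes, 3 rose and 13 fell (3 and 13 adjusted over the list alone, median -0.20, adjusted p = 0.00158, or adjusted p = 0.65 with an estimated correlation). An enoyl-CoA hydratase of branched-chain breakdown (peg.4173) fell from 235 ± 32.6 to 11.8 ± 3.67 CPM. The 49 amino acid transport genes had 0 that rose and 10 that fell (0 and 10 adjusted over the list alone, median -0.17, adjusted p = 0.0109, or adjusted p = 0.43 with an estimated correlation).

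From 24 to 48 h at 25 °C the phosphate-binding DING protein (peg.4496) rose 82-fold, from 27.7 ± 0.531 to 2270 ± 323 CPM (6.36, adjusted p = 3.28e-11), and acid phosphatase (peg.5237) from 16.6 ± 0.368 to 555 ± 234 CPM. ExbB- and ExbD-type genes (peg.4514 and peg.4515), of a type that energises outer membrane transport, and their neighbours in numbering (peg.4513, peg.4516 and peg.4517) rose by 4.63 to 5.02. Oxalate decarboxylase (peg.4710) rose from 206 ± 28.6 to 6140 ± 1640 CPM, the protease xanthomonapepsin (peg.5733) from 153 ± 17.3 to 3710 ± 337 CPM, and bacterioferritin-associated ferredoxin (peg.2699) by 4.85. Among the falls, a carbonic anhydrase-like protein (peg.4683) went from 2210 ± 52.2 to 5.9 ± 4.5 CPM (354-fold, -8.47, or -9.33 without replicate 2 of 25C_48h). Saccharopine dehydrogenase (peg.2111) fell from 4490 ± 576 to 25.3 ± 1.32 CPM (-7.47), methylmalonate-semialdehyde dehydrogenase (peg.5583), an enzyme of valine breakdown, from 1400 ± 107 to 10.6 ± 1.87 CPM, a thiolase (peg.7276) from 1260 ± 130 to 11.3 ± 5.82 CPM and OppA (peg.3603) from 127 ± 21.2 to 0.727 ± 0.274 CPM. Replicate 2 of 25C_48h held 3-hydroxyisobutyrate dehydrogenase (peg.5584) at -8.36 (-9.48 without it) and peg.7278 at -7.15 (-8.08 without it), and without replicate 3 OppF (peg.3607) went from -7.39 to -8.08. The 2 remaining large falls were peg.431 (-7.80) and peg.6918 (-6.63).

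Over these 24 h at 25 °C 2158 genes rose and 2141 fell (985 and 1086 at least 2-fold), with 63.46% of genes fully separated (chance 10%). Among 32 phosphate starvation genes, 21 rose and 6 fell (21 and 6 adjusted over the list alone, median 1.10, adjusted p = 7.02e-04, or adjusted p = 0.451 with an estimated correlation). PstS (peg.7124) rose from 267 ± 11.4 to 1760 ± 312 CPM and phospholipase C (peg.88) from 16.9 ± 2.62 to 259 ± 20.9 CPM. The 27 terminal oxidase genes had 17 that rose and 4 that fell (18 and 4 adjusted over the list alone, median 1.00, adjusted p = 0.00194, or adjusted p = 0.412 with an estimated correlation). Cytochrome d oxidase subunit II (peg.3668), of a high-affinity oxidase, rose from 16.7 ± 3.03 to 104 ± 3.27 CPM. Cytochrome o oxidase subunit III (peg.3241) fell from 282 ± 9.32 to 69 ± 10.3 CPM. Of 37 flagellar genes, 19 rose and 3 fell (19 and 3 adjusted over the list alone, median 0.69, adjusted p = 0.00511, or adjusted p = 0.108 with an estimated correlation). Of 29 nitrogen assimilation genes, 13 rose and 2 fell (13 and 2 adjusted over the list alone, median 0.69, adjusted p = 0.0356, or adjusted p = 0.412 with an estimated correlation). NtrB (peg.2585), a nitrogen sensor, rose from 69.4 ± 0.908 to 263 ± 35.5 CPM, and the list did not pass without replicate 1 of 25C_24h (adjusted p = 0.0555) or replicate 2 of 25C_48h (0.052). Among 124 phage and mobile element genes, 65 rose and 18 fell (66 and 18 adjusted over the list alone, median 0.70, adjusted p = 0.00194, or adjusted p = 0.451 with an estimated correlation). Of 20 type III secretion genes, 0 rose and 15 fell (0 and 15 adjusted over the list alone, median -1.5, adjusted p = 0.00194, or adjusted p = 0.412 with an estimated correlation). The 22 nonribosomal peptide and polyketide genes had 1 that rose and 14 that fell (1 and 15 adjusted over the list alone, median -1.34, adjusted p = 8.95e-06, or adjusted p = 0.412 with an estimated correlation). The polyketide synthase peg.2172 fell from 1670 ± 244 to 92.5 ± 4.22 CPM. Among 57 aromatic catabolism genes, 7 rose and 27 fell (7 and 27 adjusted over the list alone, median -0.48, adjusted p = 7.02e-04, or adjusted p = 0.412 with an estimated correlation). Among 82 fatty acid genes, 9 rose and 38 fell (9 and 38 adjusted over the list alone, median -0.55, adjusted p = 7.02e-04, or adjusted p = 0.451 with an estimated correlation).

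The step from 24 to 30 h at 30 °C moved fewer genes. MetW (peg.43), named for methionine synthesis, rose from 8.77 ± 0.754 to 76.8 ± 33.8 CPM (3.13, adjusted p = 0.00589) and homoserine O-acetyltransferase (peg.42) from 26 ± 4.08 to 189 ± 62.3 CPM. A maltodextrin-binding protein (peg.4388) rose from 41.4 ± 15.9 to 295 ± 27.4 CPM (adjusted p = 9.45e-08) and peg.4492 by 2.66. Threonine dehydrogenase (peg.6614) rose by 2.92 (3.75 without replicate 2 of 30C_24h), a call that ended without replicate 1 (adjusted p = 0.0705) or 3 (0.0752) of 30C_24h or replicate 2 (0.0968) or 3 (0.0631) of 30C_30h. Sulfide:quinone oxidoreductase (peg.2152) fell from 864 ± 230 to 68.2 ± 39.2 CPM (-3.66), which ended without replicate 2 of 30C_24h (0.0727) or replicate 2 (0.118) or 3 (0.0983) of 30C_30h. Its neighbour in numbering peg.2153 fell by 3.60 (4.24 without replicate 1 of 30C_30h), ending without replicate 2 (0.0664) or 3 (0.0553) of 30C_30h. Ornithine cyclodeaminase (peg.6208) fell by 3.65, or by 1.69 without replicate 2 of 30C_24h, and its call ended without replicate 2 (0.0582) or 3 (0.0529) of 30C_30h. BetI (peg.4031) fell by 3.32, or by 2.18 without replicate 2 of 30C_24h. The gene peg.3279 fell by 3.51, or by 1.95 without replicate 2 of 30C_24h (0.154), and its call ended without replicate 1 (0.1), 2 (0.0884) or 3 (0.106) of 30C_30h.

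In this step 346 genes rose and 441 fell (132 and 95 at least 2-fold), with 29.98% of genes fully separated (chance 10%). Leaving out 1 library in turn gave 362 to 968 genes, the lowest without replicate 2 of 30C_30h, 377 without replicate 2 of 30C_24h and 474 without replicate 3 of 30C_30h, and a fit of these 6 libraries alone gave 493. Under library totals 57.30% of the genes past the test rose, in place of 43.96%. The 32 phosphate starvation genes had 21 that rose and 0 that fell (24 and 0 adjusted over the list alone, median 0.75, adjusted p = 1.86e-17, or adjusted p = 0.128 with an estimated correlation). An aminoethylphosphonate transporter gene (peg.3824) rose from 50 ± 19.7 to 178 ± 10.1 CPM. Among 37 flagellar genes, 1 rose and 1 fell (1 and 1 adjusted over the list alone, median 0.22, adjusted p = 0.0321, or adjusted p = 0.192 with an estimated correlation). Among 28 sulfur assimilation genes, 3 rose and 0 fell (3 and 0 adjusted over the list alone, median 0.34, adjusted p = 0.0392, or adjusted p = 0.562 with an estimated correlation). Of 13 sugar transport genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone, median 0.36, adjusted p = 0.0454, or adjusted p = 0.562 with an estimated correlation). Without single libraries 3 of these lists did not pass: flagella without replicate 2 of 30C_24h (adjusted p = 0.0782) or replicate 1 of 30C_30h (0.0759), sulfur without replicates 1 (0.114) or 3 (0.126) of 30C_24h or replicate 2 of 30C_30h (0.098), and sugar transport without replicates 1 (0.0729) or 3 (0.105) of 30C_24h or replicates 1 (0.105) or 2 (0.0753) of 30C_30h.

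Of 56 ribosomal protein genes, 0 rose and 36 fell (0 and 49 adjusted over the list alone, median -0.56, adjusted p = 1.95e-21, or adjusted p = 0.458 with an estimated correlation). Among 15 translation factor genes, 0 rose and 7 fell (0 and 9 adjusted over the list alone, median -0.40, adjusted p = 3.04e-05, or adjusted p = 0.458 with an estimated correlation). The 11 ATP synthase genes had 0 that rose and 0 that fell (0 and 0 adjusted over the list alone, median -0.24, adjusted p = 0.0321, or adjusted p = 0.562 with an estimated correlation). This call rested on single libraries, with adjusted p = 0.138 without replicate 3 of 30C_24h and 0.0789 without replicate 2 of 30C_30h. With 0 genes past by edgeR, 3 lay lower at an unadjusted p under 0.05, and 0 passed by DESeq2 or limma-voom. The 15 NADH dehydrogenase genes had 0 that rose and 5 that fell (0 and 8 adjusted over the list alone, median -0.33, adjusted p = 4.75e-05, or adjusted p = 0.458 with an estimated correlation). NuoA (peg.2753) fell from 228 ± 35.8 to 133 ± 27.6 CPM, a call that ended without replicate 2 of 30C_30h (adjusted p = 0.0656). Among 31 chaperone and heat shock genes, 1 rose and 11 fell (1 and 15 adjusted over the list alone, median -0.30, adjusted p = 2.42e-04, or adjusted p = 0.458 with an estimated correlation). RpoH (peg.3351), the heat shock sigma factor, fell from 1190 ± 364 to 543 ± 1.89 CPM. Of 12 cold shock genes, 0 rose and 3 fell (0 and 5 adjusted over the list alone, median -0.28, adjusted p = 0.0146, or adjusted p = 0.458 with an estimated correlation). The 22 reference genes had 1 that rose and 6 that fell (2 and 7 adjusted over the list alone, median -0.25, adjusted p = 0.0213, or adjusted p = 0.626 with an estimated correlation). Without replicate 3 of 30C_24h the reference list did not pass (adjusted p = 0.0866).

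From 24 to 48 h at 30 °C a siderophore-type set rose from near 0. The MbtH-like chaperone of peptide synthetases (peg.1949) had 2 reads in 30C_24h and 1064 in 30C_48h, a ratio of CPM of 450 (95% counting interval 124 to 3720, exact binomial). The SyrP-like protein peg.1950 rose from 0.734 ± 0.316 to 81.6 ± 38.1 CPM (6.74). The synthetase peg.1957 rose by 5.47 and the hydroxamate binding protein peg.1954 by 5.80, or by 6.39 without replicate 2 and 5.15 without replicate 3 of 30C_24h. The manganese transporter MntH (peg.4711) rose 60.6-fold, from 34.4 ± 3.42 to 2090 ± 526 CPM (adjusted p = 7.25e-15), oxalate decarboxylase (peg.4710) from 118 ± 3.22 to 6140 ± 1240 CPM, xanthomonapepsin (peg.5733) from 30 ± 7.07 to 1780 ± 424 CPM and the ExbB-type gene peg.4514 from 4.61 ± 1.27 to 212 ± 31.1 CPM. The genes peg.4492 and peg.4493 rose by 5.54 and 5.49. The tellurium resistance gene TerD (peg.6577) fell 46.6-fold, from 269 ± 30.2 to 5.79 ± 1.22 CPM (-5.54, adjusted p = 4.79e-16). TerB (peg.6578), TerA (peg.6579), peg.6576, peg.6580 and peg.6581 (citrate lyase-like) fell by 4.89 to 5.43. The gene peg.6582 fell by 5.10 (5.73 without replicate 2 of 30C_48h). The carbonic anhydrase-like protein peg.4683 fell 518-fold, from 3390 ± 556 to 6.57 ± 0.764 CPM (-9.02). Ornithine cyclodeaminase (peg.6208) fell by 6.34, or by 4.41 without replicate 2 of 30C_24h, and peg.3279 by 5.30, or by 3.76 without that library and 6.68 without replicate 1 of 30C_48h.

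Over 24 to 48 h at 30 °C 1442 genes rose and 1409 fell (620 and 441 at least 2-fold), with 49.45% of genes fully separated (chance 10%). Scaling by library totals shifted the median of all genes by 0.18 and made 67.13% of the changed genes rise, in place of 50.58%. Among 56 iron uptake and storage genes, 33 rose and 8 fell (33 and 9 adjusted over the list alone, median 1.35, adjusted p = 5.87e-06, or adjusted p = 0.383 with an estimated correlation). The TonB-dependent receptor peg.4516 rose from 3 ± 1.38 to 129 ± 15.2 CPM. The iron-binding protein peg.1348 fell from 76.9 ± 10.6 to 11.1 ± 1.67 CPM. Of 32 phosphate starvation genes, 25 rose and 2 fell (25 and 2 adjusted over the list alone, median 0.71, adjusted p = 1.71e-08, or adjusted p = 0.255 with an estimated correlation). The transporter gene peg.3824 rose from 50 ± 19.7 to 464 ± 77.6 CPM and phospholipase C (peg.88) from 12.6 ± 2.83 to 112 ± 14.9 CPM. Among 29 nitrogen assimilation genes, 13 rose and 0 fell (13 and 0 adjusted over the list alone, median 0.55, adjusted p = 0.0018, or adjusted p = 0.195 with an estimated correlation). The urease alpha subunit (peg.1026), which frees ammonia from urea, rose from 2.84 ± 0.181 to 23.7 ± 2.71 CPM. The 37 flagellar genes had 16 that rose and 2 that fell (17 and 2 adjusted over the list alone, median 0.42, adjusted p = 0.034, or adjusted p = 0.195 with an estimated correlation). Without replicate 2 of 30C_24h (adjusted p = 0.0771) or replicate 1 of 30C_48h (0.0511) the flagella list did not pass. Of 84 type VI secretion genes, 22 rose and 8 fell (22 and 8 adjusted over the list alone, median 0.21, adjusted p = 0.0443, or adjusted p = 0.383 with an estimated correlation). VgrG (peg.4966), a spike protein, rose from 221 ± 42.5 to 679 ± 70.9 CPM, and the list did not pass without replicate 2 of 30C_24h (adjusted p = 0.091) or replicate 2 of 30C_48h (0.0817).

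Another 11 lists went down over these hours. Among 56 ribosomal protein genes, 0 rose and 52 fell (0 and 55 adjusted over the list alone, median -0.75, adjusted p = 1.62e-13, or adjusted p = 0.383 with an estimated correlation). The 15 translation factor genes had 0 that rose and 12 that fell (0 and 13 adjusted over the list alone, median -0.63, adjusted p = 1.38e-04, or adjusted p = 0.383 with an estimated correlation). Of 11 ATP synthase genes, 0 rose and 9 fell (0 and 9 adjusted over the list alone, median -1.17, adjusted p = 4.08e-07, or adjusted p = 0.195 with an estimated correlation). Of 15 NADH dehydrogenase genes, 0 rose and 5 fell (0 and 5 adjusted over the list alone, median -0.32, adjusted p = 0.0237, or adjusted p = 0.531 with an estimated correlation). Without replicate 2 of 30C_24h this list did not pass (adjusted p = 0.0543). Among 25 TCA cycle and glyoxylate genes, 4 rose and 13 fell (4 and 14 adjusted over the list alone, median -0.51, adjusted p = 0.00427, or adjusted p = 0.383 with an estimated correlation). The 31 chaperone and heat shock genes had 4 that rose and 18 that fell (4 and 19 adjusted over the list alone, median -0.41, adjusted p = 0.00257, or adjusted p = 0.383 with an estimated correlation). Among 12 cold shock genes, 0 rose and 5 fell (0 and 5 adjusted over the list alone, median -0.46, adjusted p = 0.034, or adjusted p = 0.383 with an estimated correlation).

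Among 20 type III secretion genes, 0 rose and 11 fell (0 and 11 adjusted over the list alone, median -1.01, adjusted p = 0.00661, or adjusted p = 0.383 with an estimated correlation). Of 22 nonribosomal peptide and polyketide genes, 4 rose and 10 fell (4 and 10 adjusted over the list alone, median -0.42, adjusted p = 0.0101, or adjusted p = 0.391 with an estimated correlation). The polyketide synthases peg.2172 and peg.2171 fell from 1050 ± 215 to 111 ± 15.8 and from 1440 ± 104 to 157 ± 21.9 CPM. Of 11 branched-chain amino acid synthesis genes, 0 rose and 5 fell (0 and 5 adjusted over the list alone, median -0.16, adjusted p = 0.01, or adjusted p = 0.383 with an estimated correlation). The mean was -0.57, and under library totals the median was 0.01, of the opposite sign. Ketol-acid reductoisomerase (peg.2769) fell from 728 ± 86.1 to 233 ± 52.7 CPM. Of 22 reference genes, 2 rose and 14 fell (2 and 15 adjusted over the list alone, median -0.52, adjusted p = 0.0018, or adjusted p = 0.383 with an estimated correlation).

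**Figure D4:**
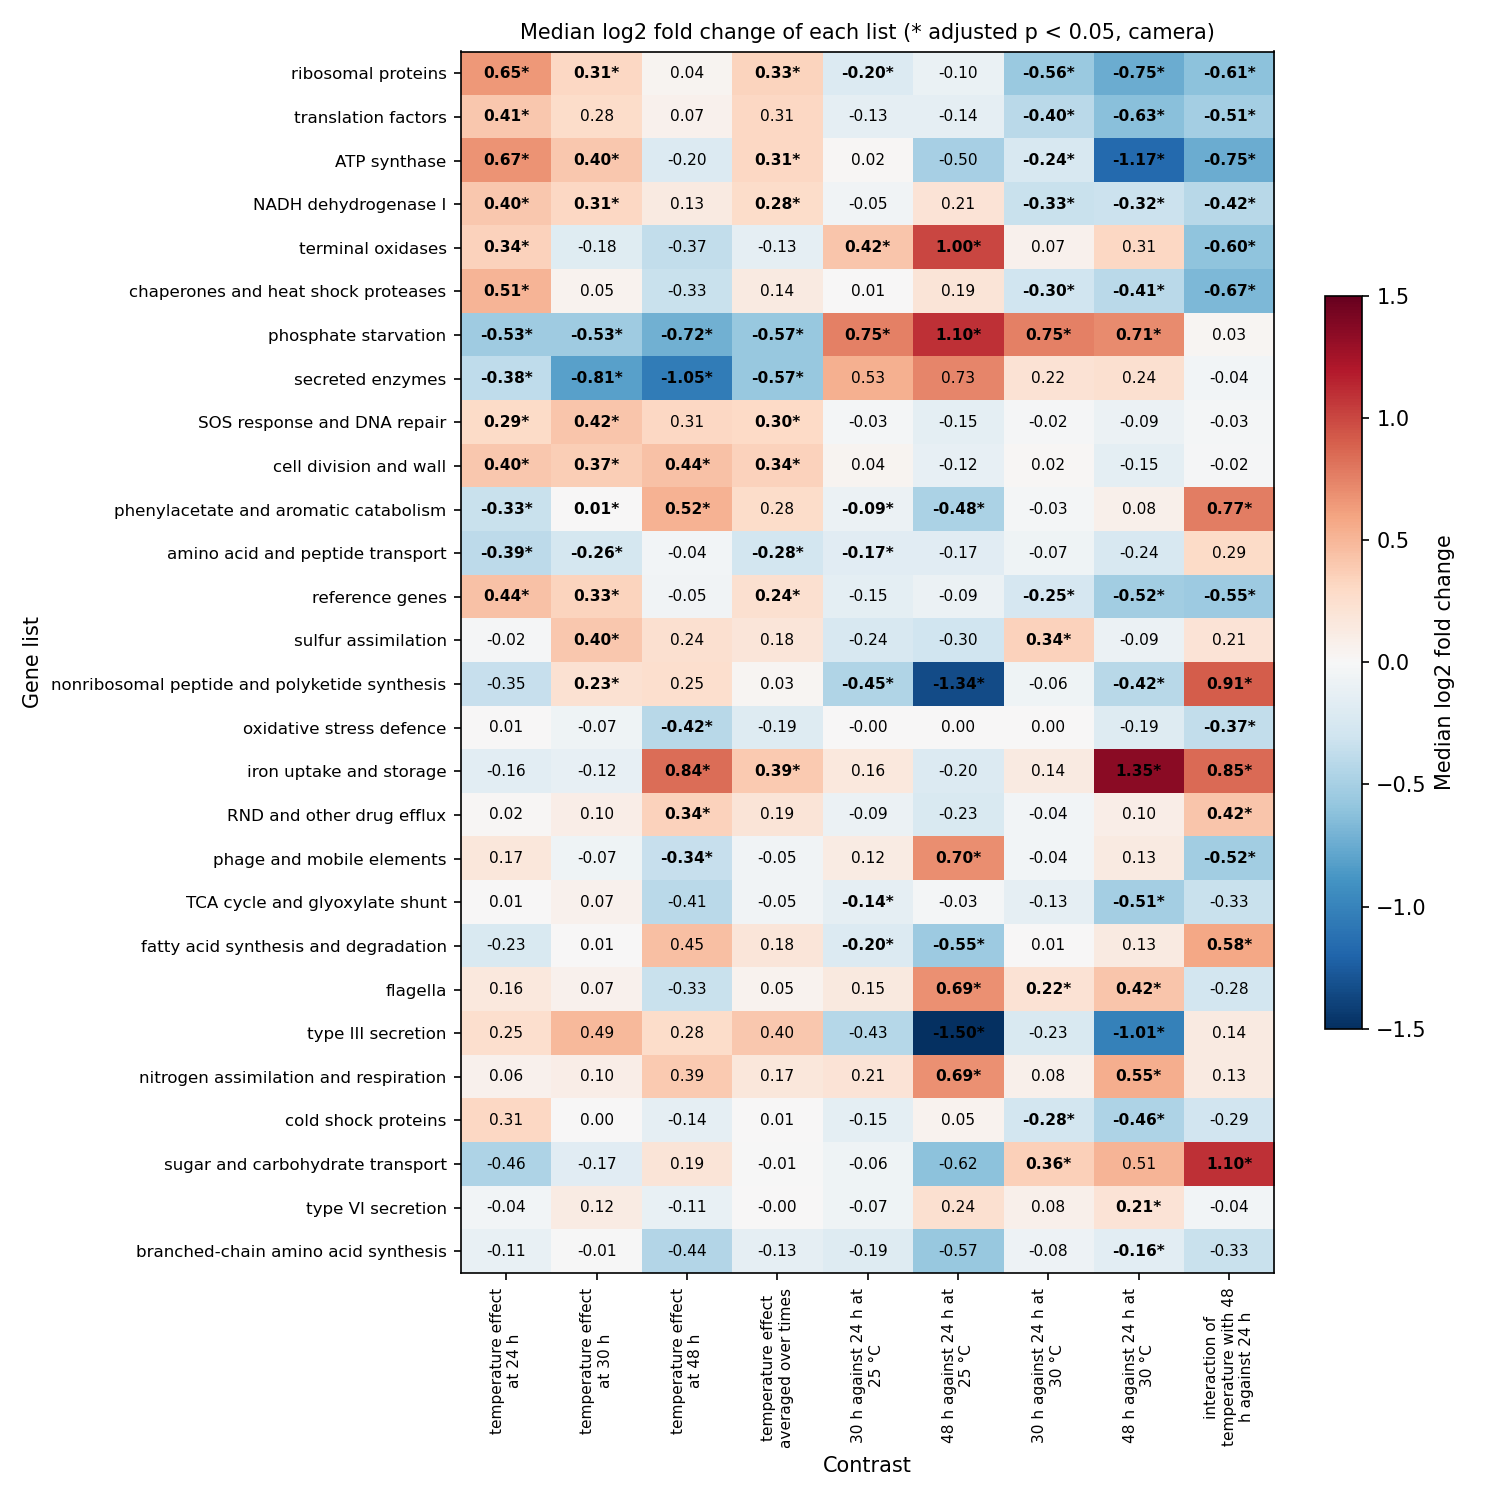
Cells give the median log2 fold change of 28 gene lists (vertical axis) in 9 contrasts (horizontal axis), with an asterisk where camera gave an adjusted p under 0.05. The ribosomal protein list stands at 0.65 for temperature at 24 h and at -0.75 for 48 h against 24 h at 30 °C.

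Whether the change from 24 to 48 h differed between temperatures was tested as an interaction, positive where the change was more upward at 30 °C. It passed for 2856 genes, 1509 positive and 1347 negative (1003 and 514 at least 2-fold). The tyrosine enzyme peg.431 had the largest value, 8.21 (SE 0.59, adjusted p = 1.04e-07), with peg.923 at 7.16 (6.40 without replicate 3 of 30C_48h), saccharopine dehydrogenase (peg.2111) at 7.09, OppF (peg.3607) at 7.04 (7.72 without replicate 3 of 25C_48h) and a branched-chain amino acid binding protein (peg.6293) at 7.0. Negative values were found for ornithine cyclodeaminase (peg.6208, -5.14, or -3.24 without replicate 2 of 30C_24h), BetI (peg.4031, -3.72, or -2.62 without that library), a mobile element protein (peg.6536, -2.63) and isocitrate lyase (peg.2477, -2.49, or -1.72 without replicate 2 of 25C_48h and -3.10 without replicate 2 of 25C_24h). The luciferase-type protein peg.4146 (-3.38, adjusted p = 0.043) lost its call without any 1 of 13 libraries: 25C_24h replicates 1 (0.0766), 2 (0.0754) and 3 (0.0676), 25C_30h replicates 2 (0.0506) and 3 (0.0518), 25C_48h replicates 1 (0.0548), 2 (0.0594) and 3 (0.0696), 30C_24h replicate 2 (-2.00, 0.142), 30C_30h replicate 1 (0.0523), and 30C_48h replicates 1 (0.0704), 2 (0.0719) and 3 (0.0871). Under library totals the median of all genes moved by 0.21 and 70.17% of the genes past the test were positive, in place of 52.84%.

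Positive interactions were found for 6 lists. Of 56 iron uptake and storage genes, 26 were positive and 1 negative (27 and 1 adjusted over the list alone, median 0.85, adjusted p = 2.85e-05, or adjusted p = 0.308 with an estimated correlation). Of 22 nonribosomal peptide and polyketide genes, 14 were positive and 1 negative (15 and 1 adjusted over the list alone, median 0.91, adjusted p = 7.26e-05, or adjusted p = 0.308 with an estimated correlation). The synthetases peg.1957 and peg.1958 stood at 5.91 and 5.14, and the polyketide synthase peg.2074 at -0.70. Of 57 aromatic catabolism genes, 30 were positive and 1 negative (30 and 1 adjusted over the list alone, median 0.77, adjusted p = 1.07e-05, or adjusted p = 0.308 with an estimated correlation). Of 82 fatty acid genes, 26 were positive and 6 negative (27 and 6 adjusted over the list alone, median 0.58, adjusted p = 0.00108, or adjusted p = 0.436 with an estimated correlation). Of 13 sugar transport genes, 8 were positive and 0 negative (8 and 0 adjusted over the list alone, median 1.10, adjusted p = 0.00468, or adjusted p = 0.354 with an estimated correlation). Of 109 drug efflux genes, 27 were positive and 5 negative (27 and 5 adjusted over the list alone, median 0.42, adjusted p = 0.0468, or adjusted p = 0.597 with an estimated correlation). That call ended without replicate 1 of 25C_24h (adjusted p = 0.0716), replicate 1 (0.0736) or 3 (0.0524) of 25C_48h, replicate 1 (0.0683) or 3 (0.0667) of 30C_24h or replicate 1 of 30C_48h (0.0584).

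Negative interactions were found for 9 lists. Of 56 ribosomal protein genes, 0 were positive and 29 negative (0 and 31 adjusted over the list alone, median -0.61, adjusted p = 5.54e-07, or adjusted p = 0.676 with an estimated correlation). Of 15 translation factor genes, 0 were positive and 8 negative (0 and 8 adjusted over the list alone, median -0.51, adjusted p = 0.00632, or adjusted p = 0.552 with an estimated correlation). Of 11 ATP synthase genes, 0 were positive and 9 negative (0 and 9 adjusted over the list alone, median -0.75, adjusted p = 0.00233, or adjusted p = 0.308 with an estimated correlation). Of 15 NADH dehydrogenase genes, 0 were positive and 6 negative (0 and 6 adjusted over the list alone, median -0.42, adjusted p = 0.0235, or adjusted p = 0.676 with an estimated correlation). It did not pass without replicate 1 of 25C_48h (adjusted p = 0.0738). Of 27 terminal oxidase genes, 2 were positive and 14 negative (2 and 15 adjusted over the list alone, median -0.60, adjusted p = 0.00115, or adjusted p = 0.308 with an estimated correlation). Cytochrome d oxidase subunit II (peg.3668) stood at -1.86 and cytochrome o oxidase subunit III (peg.3241) at 1.24. Of 31 chaperone and heat shock genes, 2 were positive and 17 negative (2 and 20 adjusted over the list alone, median -0.67, adjusted p = 2.42e-04, or adjusted p = 0.308 with an estimated correlation). Of 39 oxidative stress genes, 6 were positive and 15 negative (6 and 16 adjusted over the list alone, median -0.37, adjusted p = 0.0395, or adjusted p = 0.354 with an estimated correlation). Superoxide dismutase (peg.3042) stood at -1.27, and the list did not pass without replicate 1 (adjusted p = 0.0584) or 3 (0.0567) of 30C_48h. Of 124 phage and mobile element genes, 2 were positive and 34 negative (1 and 23 adjusted over the list alone, median -0.52, adjusted p = 2.85e-05, or adjusted p = 0.308 with an estimated correlation). Of 22 reference genes, 1 were positive and 10 negative (1 and 10 adjusted over the list alone, median -0.55, adjusted p = 0.00632, or adjusted p = 0.637 with an estimated correlation).

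Changes shared between comparisons were counted against the number that independent calls would give. From 24 to 48 h 884 genes rose at both temperatures (426 by chance), 746 fell at both (413) and 277 went opposite ways (840), and the changes correlated across genes at 0.55, where genes are not independent replicates. For 24 to 30 h, 173 rose at both (31), 68 fell at both (28) and 14 went opposite ways (61), with a correlation of 0.27. Temperature raised 729 genes at both 24 and 30 h (211 by chance), lowered 849 at both (272) and moved 73 in opposite directions (480), with a correlation of 0.57. Between 30 and 48 h 609 were raised at both (273), 799 lowered at both (310) and 138 opposite (588), with a correlation of 0.44. Between 24 and 48 h 555 were raised at both (373), 665 lowered at both (363) and 393 opposite (737), with a correlation of 0.22.

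By camera, 10 gene lists passed in 0 of the 9 contrasts, with 8 of their 90 tests at an unadjusted p under 0.05 and 33 past with fry. Each is given for the contrast with its lowest adjusted p. The 23 RNA polymerase and sigma factor genes, for temperature averaged over times, had 10 higher and 1 lower (median 0.23, adjusted p = 0.0724). For 48 h against 24 h at 30 °C, 41 chemotaxis genes had 12 higher and 4 lower (median 0.13, adjusted p = 0.18), and 26 arginine genes had 0 higher and 8 lower (median -0.15, or 0.04 under library totals, adjusted p = 0.0531). At 25 °C over the same hours, 14 exopolysaccharide genes had 1 higher and 8 lower (median -0.67, adjusted p = 0.0753). For temperature, 9 polyhydroxyalkanoate genes at 30 h had 1 higher and 3 lower (median -0.18, adjusted p = 0.373), 19 stringent response genes at 24 h had 9 higher and 2 lower (median 0.35, adjusted p = 0.0661), and 90 porin and outer membrane genes at 48 h had 10 higher and 23 lower (median -0.28, adjusted p = 0.0615). Averaged over times, 26 osmotic genes had 8 higher and 4 lower (median 0.01, adjusted p = 0.505). In the interaction, 4 quorum sensing genes had 0 positive and 2 negative (median -0.31, adjusted p = 0.342), and 66 fimbrial and adhesin genes had 12 positive and 4 negative (median 0.22, adjusted p = 0.143). In the 38 places where a list that passed had 0 members in 1 direction by edgeR, an unadjusted p under 0.05 gave 0 members in 34 and at most 3, and DESeq2 and limma-voom gave at most 1.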

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

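The tests of scaling, depth and single libraries below were chosen after the results were seen, and those of splits before. The change from 24 to 48 h differed between temperatures, by a tested interaction, in 2856 genes. Among single genes it was 8.21 for peg.431, 7.16 for peg.923, 7.09 for peg.2111, 7.04 for peg.3607 and 7.0 for peg.6293, and -5.14 for peg.6208, -3.72 for peg.4031, -3.38 for peg.4146, -2.63 for peg.6536 and -2.49 for peg.2477. As list medians it was -0.61 for ribosomal proteins, -0.51 for translation factors, -0.75 for ATP synthase, -0.42 for NADH dehydrogenase, -0.60 for terminal oxidases, -0.67 for chaperones, -0.37 for oxidative stress, -0.52 for phage and -0.55 for reference genes, and 0.85 for iron, 0.91 for nonribosomal peptides and polyketides, 0.42 for efflux, 0.77 for aromatic catabolism, 0.58 for fatty acids and 1.10 for sugar transport. Of 91 genes named for a large rise or fall elsewhere, 71 passed the interaction test, against 39.13% of all genes, but they were chosen in comparisons that share its libraries.

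Splits of the libraries were tested likewise, 10 per pairwise contrast, too few for a share under 0.05. The real split alone (1 of 10) reached its count of 2973, 2364, 3615, 1105, 4299, 787 and 2851 genes, with at most 1 in another. Chance labels of libraries were excluded for the averaged temperature effect (1 of 100 splits, 4096 genes, highest other 2622). They were for any difference too (1 of 100, 5875 genes, highest other 27). Chance between cultures was not tested. For the interaction (2 of 100, 2856 genes, 3736 with whole groups swapped) the splits also mix temperatures and cannot isolate it. List counts did not exclude chance. The pairwise contrasts had 13, 12, 8, 8, 9, 11 and 16 real list calls, against 13, 10, 16, 10, 19, 8 and 16 in the highest other split. Of 10 splits, 2, 1, 5, 3, 6, 1 and 3 were as large, too few where it was 1. The averaged effect had 10 lists (36 of 100 splits as large, highest other 18) and the interaction 15 (10 of 100, highest other 21).

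Ribosomal protein genes were higher at 30 than at 25 °C at 24 h, with a median of 0.65. Scaling alone moves all genes alike, yet the median of the members less that of all other genes differed by 0.66 (lower 95% limit 0.32). Camera had called this list and those below by that comparison, so it adds little. A single library was argued against by a lowest median of 0.47 (without replicate 2 of 30C_24h). Depth alone was argued against by a lower limit of 0.41 with log2 of the total count in the model, although the list fell by 0.66 per doubling of depth (SE 0.22). A faster growth at 30 °C may account for it, which was not tested.

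Iron uptake and storage genes were higher at 30 than at 25 °C at 48 h, with a median of 0.84. The lower limits were 0.82 for scaling and 0.77 for depth, and the lowest median was 0.72 (without replicate 1 of 25C_48h). These argue against depth or 1 library as the sole cause. A lower supply of iron in the older 30 °C cultures may account for it, which was not tested.

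Phosphate starvation genes were higher at 30 than at 24 h at 25 °C, with a median of 0.75. The lower limits were 0.51 for scaling and 0.49 for depth, and the lowest median was 0.73 (without replicate 1 of 25C_30h). These argue against depth or 1 library as the sole cause. Use of phosphate from the medium with time may account for it, which was not tested.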

How the results depend on the processing

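Leaving out 2 libraries together, leaving out 1 library in the list tests and, for the gene counts, scaling by library totals were alternatives chosen after the data were seen. Counts of genes past the test stayed within 1.5 times under DESeq2 size factors, library totals, no filter on low counts, DESeq2's Wald test and limma-voom, and with a replicate block that pairs libraries by number (2980 for the interaction and 69 equivalent genes in that block). Leaving out 1 library in turn gave 2413 to 3257 genes for temperature at 24 h, 1848 to 2674 at 30 h, 2984 to 4051 at 48 h and 3901 to 4360 averaged, 762 to 1323 for 30 h against 24 h and 3794 to 4539 for 48 h against 24 h at 25 °C, 362 to 968 and 2461 to 3118 for the same steps at 30 °C, 2362 to 3596 for the interaction and 5588 to 6075 for any difference. Steady strong genes numbered 147 to 163 and equivalent ones 49 to 79. Single ranges moved by more than the SD between replicates in 7 genes under library totals (peg.5727 to 0.29, peg.7112 to 0.84, peg.2209 to 0.43, peg.236 to 1.25, peg.671 to 0.86, peg.4867 to 0.58 and peg.2074 to 1.05) and in 15 values with 1 library left out. These were without replicate 1 of 25C_48h peg.5834 (0.48), without its replicate 2 peg.5727 (0.68), peg.5834 (0.81), peg.3023 (0.78), peg.2209 (0.79), peg.840 (1.51), peg.5684 (0.29), peg.5330 (0.96) and peg.2571 (1.64), without replicate 2 of 30C_48h peg.2209 (0.80), peg.7467 (0.63), peg.4867 (0.90), peg.4682 (9.78) and peg.5662 (1.77), and without replicate 2 of 30C_24h peg.6926 (0.87). Of these only peg.6926 crossed the 2-fold limit, and peg.840, peg.971, peg.972, peg.1275, peg.6258, peg.4189 and peg.7117 crossed it in some setting by less than that SD.

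A 2-fold minimum asks for larger changes and left 265, 288, 390 and 278 genes for temperature at 24, 30 and 48 h and averaged, 171 and 976 for the steps to 30 and 48 h at 25 °C, 50 and 507 for those at 30 °C, and 324 for the interaction. Fitting 6 libraries alone gave 1936 genes for 30 h against 24 h at 25 °C, 1082 of them shared, and 493 at 30 °C, 458 of them shared. The cause was not tested. By construction, wider and narrower limits changed the steady counts: the top 10% gave 327 steady and 143 equivalent genes, the top 2% gave 63 and 20, and a 1.5-fold limit gave 44 and 0, where limma had 8 at an unadjusted p under 0.05. Without replicate 2 of 30C_24h and replicate 2 of 25C_48h, each with the highest chi-square values of its group, the counts were 3010, 2891, 4268 and 4388 for temperature, 1596 and 4709 at 25 °C, 598 and 2891 at 30 °C, and 3729 for the interaction. With replicate 1 of 25C_48h left out in place of its replicate 2, they were 3018, 2918, 3288 and 4162, 1597 and 4021, 589 and 2906, and 2576.

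With an estimated correlation, camera called 0 lists in each of the 9 contrasts. Fry, which asks another question, called 22, 16, 24 and 27 lists for temperature at 24, 30 and 48 h and averaged, 9 and 22 for the steps at 25 °C, 11 and 27 at 30 °C, and 19 for the interaction. It reversed 1 list, terminal oxidases for temperature averaged over times (adjusted p = 0.0459), and the cause was not tested. Leaving out 1 library gave 12 to 17, 10 to 12, 8 to 12 and 7 to 12 lists for temperature at 24, 30 and 48 h and averaged, 7 to 10 and 8 to 13 at 25 °C, 7 to 12 and 13 to 19 at 30 °C, and 13 to 17 for the interaction. Named genes kept their direction in every alternative run and their call in 22016 values with 1 library left out (790 lost), 1264 under DESeq2 size factors (3 lost), 1221 under library totals (46 lost), 1257 with no filter (10 lost), 1248 with limma-voom (19 lost), 1264 with DESeq2's Wald test (2 lost), 1260 with the replicate block (7 lost), 886 with the compared groups alone (75 lost), 1208 without replicate 2 of both 30C_24h and 25C_48h (59 lost), 1207 with replicate 1 of 25C_48h out in its place (60 lost) and 457 with the 2-fold minimum (810 lost). Of 1267 named values 262 moved over 1.5-fold or lost their call without 1 library (178 of 689 largest changes). The filter on ribosomal RNA and tRNA genes and the use of lengths were not run, since the table holds neither. Depth limited genes such as peg.1949, with 2 reads in 30C_24h.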

Other observations

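The runs of features and their rule below were chosen after the results were seen, and the tests of the hypotheses, but for those marked, before. Changes of at least 4-fold came in runs of at least 5 features next to each other in number, and numbering does not establish that they lie together on the genome. From 24 to 48 h there were 23 runs at 25 °C (165 genes, 8 rising and 15 falling, the longest of 17) and 15 runs at 30 °C (121 genes, 9 rising and 6 falling, the longest of 21), where 1000 shuffled orders gave at most 1. A run with polyketide synthases from peg.2165 to peg.2180 (16 genes) fell with a median of -3.40 at 25 °C and -3.03 at 30 °C. One with tellurium resistance genes, peg.6576 to peg.6585 (10 genes), fell with -3.53 and -5.11. Branched-chain amino acid degradation from peg.4169 to peg.4174 fell with -4.91 and -2.75. Rising runs held secretion and TonB-type genes (peg.4510 to peg.4526 at 25 °C, median 3.60, and peg.4507 to peg.4527 at 30 °C, median 5.03) and iron(II) transport genes (peg.2706 to peg.2710, 2.93 and 3.56). The 7 runs counted at 30 °C but not at 25 °C included hemin uptake from peg.3733 to peg.3737 (3.58 at 30 °C), siderophore genes from peg.1948 to peg.1955 (5.82) and aminoethylphosphonate transport from peg.3821 to peg.3830 (3.21). At 25 °C 1 of 5, 3 of 8 and 10 of 10 of their genes rose (1, 0 and 0 fell), and the interaction was positive in 4, 6 and 7.

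A hypothesis was that 30 °C cultures stand further along the time course at the same hour. At 24 h the temperature difference correlated across genes with the later change from 30 to 48 h at 25 °C, which shares no library with it, at 0.22, between the bounds set for and against, so this stays open. At 30 h it correlated with the change from 24 to 48 h at 25 °C at -0.19, which argues against it there. A further hypothesis, that replicate 1 of 25C_48h stood further along than replicate 2, stays open. Their difference correlated with the change from 24 to 48 h at 30 °C at -0.01, under the bound set against it, but that bound relied on a course that differs at 25 °C. With courses at 25 °C, chosen after the results were seen, it correlated at 0.15 (24 to 30 h) and 0.42 (24 h to replicate 3 of 25C_48h), and on the first component replicates 1, 3 and 2 lay at 76.11, 64.08 and 49.18. Genes are not independent replicates in these correlations.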
